A study of Mus musculus with 2 samples.

How the data were processed

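Genomic DNA of mouse embryonic stem (ES) cells of strain 129SvEv was sheared to short fragments, and fragments that hold 5-hydroxymethylcytosine (5hmC) were pulled down and sequenced, per the labels' protocols. The pull-down was a chemical one: the 5hmC was tagged with biotin, per the labels. There were 2 libraries, 1 from cells kept with 100 µM ascorbic acid (AA, vitamin C) for 24 h and 1 whose label names no incubation. The series' design sets cells with AA against cells without it, so the second library was placed in the group without AA. A single list of enriched regions (peaks) was deposited for each library.

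The file headers raise a doubt about which list belongs to which sample. The list recorded for the AA sample carries in its header the run name and input of the other sample, and the list recorded for the sample without AA carries those of the AA sample, so 2 of 2 headers disagree with the record. The assignment of the record was kept. The lists are called the AA-labelled list and the no-AA-labelled list, and any direction between them turns round if the headers are right.

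The authors aligned the reads with BWA 0.5.9-r16 to mouse build mm9 and called peaks with MACS 1.4.2, per the submitters' processing notes. The aligner settings and the treatment of reads that map to several places are not given in the sources used here. Each list was called on 1 library alone with no control or input library, at a p cutoff of 1e-05, a band width of 300 bp, an effective genome size of 2.7 Gb and a regional background taken over 10000 bp, per the file headers. Tags (aligned reads of 101 bp) were kept once per position, per the file headers. That left 11907082 of 15767993 tags in the AA-labelled library and 18398162 of 27083528 tags in the no-AA-labelled library. The fragment length that MACS estimated was 229 bp in the AA-labelled library and 165 bp in the other, per the file headers.

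The deposited lists give for each peak its start and end (counted from 1), its length, a count of tags, a score of 10 times the −log10 of the Poisson p-value (50 at the cutoff, at most 3100) and a fold enrichment. The deposited tag counts are whole numbers and are not scaled to library size. The deposited −log10 p-values and the fold enrichment, a ratio to the caller's background, were set by the authors' caller within each library. The values per peak are therefore the authors' own. The lists hold only regions past the cutoff, so a region missing from a list is a region not called, not one without 5hmC. Because every library is scaled to its own background or its own tag total, these values do not measure the total level of 5hmC in the genome.

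Peaks were matched with bedtools 2.31.1, and a peak was called shared if it overlapped a peak of the other list by at least 1 bp. The chance level was the mean over 100 random shifts of the AA-labelled peaks along their chromosomes, wrapped at the ends of the covered stretch. For peaks that overlapped one to one, tags were divided by peak length in kb and by the library's kept tags in units of 1000000, and the log2 ratio of the AA-labelled to the no-AA-labelled value was taken. Peaks per chromosome were divided by the end of the last peak on that chromosome, which stands in for its length. Windows of 1 Mb took each peak by its midpoint. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. On simulated lists of 57827 peaks in which 60.0% had a true counterpart, 60.1% were found shared, and a true log2 ratio of 0.50 came back as 0.51. There each counterpart kept its length and was moved by less than it, and all other peaks were placed apart from any peak. The share was thus set by the design. The simulation checks the code only, not the effects of a calling cutoff or of unequal peak and fragment lengths.

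With 1 library per group there is no replicate error, and no test between the groups was made. Intervals are 95% exact intervals: Poisson for a count, Clopper-Pearson for a share, the same conditional on the sum of both counts for a ratio of counts, and order statistics for a median over pairs. They cover counting error only, or for a median the spread over pairs only. Peaks, pairs and windows of 1 library are not replicates. PCR copies beyond 1 per position were removed, but tags without molecular identifiers are not certain to be separate molecules.

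The regions named in the text were fixed by a rule before the data were examined. The rule took the 10 unshared peaks of highest fold enrichment in each list and the 10 shared pairs of highest mean fold enrichment. It also took the 5 highest and 5 lowest tag density ratios among pairs with at least 30 tags in 1 library, the 3 windows of 1 Mb with the largest scaled difference each way, and every chromosome. Regions chosen after their values were seen are marked as such. Alternatives were stricter cutoffs (p of at most 1e-10, or a fold enrichment of at least 10), other overlap rules, other tag measures and scalings, and windows of 250 kb or 5 Mb. An FDR cutoff could not be tried, since the lists hold no FDR column. Peaks at promoters, in genes and in gene lists were planned but not analysed here. The gene table at hand is of build GRCm38, and 29 and 43 peaks of the lists lie on chromosome 1 beyond its last gene, so it was not used for positions.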

Results

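The series measured where 5hmC lies in the genome of mouse ES cells with or without ascorbic acid. 5hmC is the first product of the oxidation of 5-methylcytosine by the Tet dioxygenases, enzymes that use iron and 2-oxoglutarate, and ascorbic acid is a reducing agent known to support enzymes of this family. The data were 2 peak lists from 1 library each, the AA-labelled list (100 µM AA for 24 h) and the no-AA-labelled list. The header of each list names the other sample, so every direction given here holds only for the lists as recorded. The AA-labelled library held 11907082 tags after removal of duplicates and the no-AA-labelled library 18398162, which is 1.55 times as many. Duplicates made up 24.5% and 32.1% of their tags. All positions are on mouse build mm9, and no gene annotation of that build was used here, so positions carry no gene names.

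The first comparison asked how much of the genome was enriched for 5hmC with and without AA. The AA-labelled list held fewer peaks that were longer and carried a larger part of the library. It had 57827 peaks (95% Poisson interval 57357 to 58300) against 63834 (63340 to 64331), a ratio of 0.906 (0.896 to 0.916). These peaks covered 68.8 Mb in the AA-labelled list and 57.1 Mb in the other, a ratio of 1.21. They held 16.9% of the kept tags against 11.7%, at a mean of 2.46 against 2.06 tags per kb and 1000000 kept tags, with Clopper-Pearson intervals of 16.9% to 16.9% and 11.7% to 11.8%. The median peak was 1032 bp long (quartiles 798 and 1409 bp) in the AA-labelled list and 778 bp (611 and 1041 bp) in the other. The ratio of these medians was 1.33, beside a ratio of 1.39 between the fragment lengths that MACS used.

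The AA-labelled list held more peaks of high strength. Within each list, the median of the authors' fold enrichment over the local background was 7.86 (quartiles 6.12 and 9.90) in the AA-labelled list and 7.05 (5.59 and 8.66) in the no-AA-labelled list. A fold enrichment of at least 10 was reached by 12542 AA-labelled and 6656 no-AA-labelled peaks, a ratio of 1.88 (1.83 to 1.94). A p of at most 1e-10 was reached by 13247 and 11777 peaks, a ratio of 1.12 (1.10 to 1.15). The AA-labelled list was thus the shorter one at the authors' cutoff and the longer one at either stricter cutoff. With 1 library each, depth and fragment length differ together with the label, and no replicate spread is at hand. The fold enrichment and p are each library's own, set by its depth and fragment length as well as by its 5hmC.

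The second comparison asked whether the same places were enriched. Of the AA-labelled peaks, 27477 overlapped a no-AA-labelled peak, or 47.5% (Clopper-Pearson 47.1% to 47.9%), and 30350 did not. Of the no-AA-labelled peaks, 27838 were shared, or 43.6% (43.2% to 44.0%), and 35996 were not. Shifting the AA-labelled peaks along their chromosomes gave 5.33% and 4.87% by chance, and none of the 100 shifts passed 5.58% or 5.09%. In length, the lists had 25.3 Mb in common of 100.6 Mb covered by either.

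Peaks of small p were shared more often than peaks near the cutoff. Of the strongest 10% of the AA-labelled peaks by p, 89.4% were shared (88.6% to 90.2%), against 27.7% of the weakest 10% (26.5% to 28.8%). In the no-AA-labelled list the shares were 88.8% (88.0% to 89.6%) and 23.7% (22.6% to 24.7%). By fold enrichment the rise was weaker, from 39.2% in the lowest 10% to 72.6% in the highest 10% of the AA-labelled list and from 41.5% to 60.9% in the other, where the share fell to 37.3% in between. Shared AA-labelled peaks had a median of 31 tags and unshared ones 25. In the no-AA-labelled list these medians were 33 and 24 tags. Of the peaks with a p of at most 1e-10, 3163 AA-labelled and 2435 no-AA-labelled peaks had no counterpart at any strength.

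**Figure D1:**
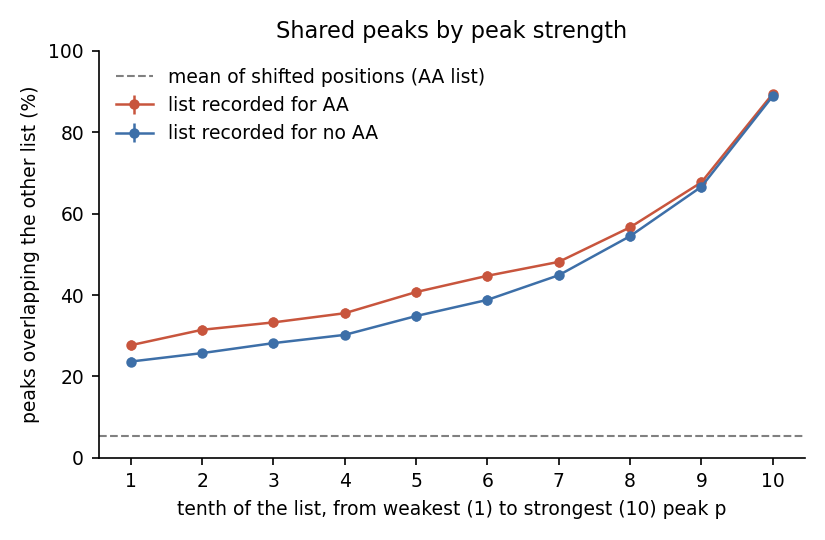
Share of peaks that overlap the other list (y axis, percent, with Clopper-Pearson 95% intervals that are mostly smaller than the points) in each class of 10% of a list ordered by peak p (x axis, weakest to strongest). The AA-labelled list (red) rises from 27.7% to 89.4% and the no-AA-labelled list (blue) from 23.7% to 88.8%, both far above the mean of 5.33% for shifted AA-labelled peaks (dashed line).

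The peak of highest fold enrichment was at the same place in both lists. This pair lay on chromosome 13 (77578040 to 77578446 in the AA-labelled list), at 38.82-fold with 88 tags in the AA-labelled library and 49.68-fold with 100 tags in the other. Next came chromosome X (166527084 to 166527633) at 34.61-fold and 46.86-fold, chromosome 6 (103598915 to 103599419) at 35.17-fold and 45.98-fold, and chromosome 18 (14261607 to 14262365) at 33.79-fold and 42.19-fold. The other 6 of these 10 pairs lay on chromosomes 14 (86598666 to 86599243), 12 (3109307 to 3111758), 1 (32434721 to 32436010), 9 (24346326 to 24346731 and 35112265 to 35113554) and X (73843765 to 73844603). These folds rank pairs by their mean, and each belongs to its own list. The largest count among them was 582 tags, in the AA-labelled peak at 35112265 on chromosome 9. Many of these peaks held more than 0.25 tags per bp, against medians of 0.0264 and 0.0349 in the AA-labelled and no-AA-labelled lists. They were both peaks of the pairs on chromosomes X (at 166527084), 6 and 9 (at 35112265), and the no-AA-labelled peak of those on chromosomes 13, 18 and 12. At such density the limit of 1 tag per position narrows the range of the counts. No input library was at hand to show what part of these tags comes from 5hmC.

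Peaks called in the AA-labelled list alone were led by chromosome 10 (64204279 to 64205220), with 33 tags (Poisson interval 22.7 to 46.3) and a fold enrichment of 20.44. It was followed by chromosome 13 (25674626 to 25675768) at 20.38-fold with 28 tags and chromosome 2 (122781649 to 122782489) at 20.01-fold with 32 tags. The remaining 7 of the first 10, at 19.41-fold to 19.80-fold, lay on chromosomes 4 (109405055 to 109405663 and 121820132 to 121820690), 6 (25042820 to 25043588 and 69867694 to 69868742), 13 (101710357 to 101711489), 7 (63971684 to 63972227) and 8 (69976204 to 69977275). Peaks called in the no-AA-labelled list alone were led by 2 sites on chromosome 14. These were 14678986 to 14679598, with 35 tags (24.4 to 48.7) at 25.79-fold, and 106846096 to 106846726, with 32 tags at 23.12-fold. A further site on chromosome 14 (107884124 to 107884734) at 17.57-fold was also among the first 10. The other 7, at 16.90-fold to 18.68-fold, lay on chromosomes 12 (20064516 to 20065182 and 63992807 to 63993491), X (150940189 to 150940638), 16 (64952272 to 64953040), 4 (24405695 to 24406150), 8 (66364015 to 66364665) and 11 (40623400 to 40624106). For such a site the tag count of the other library is not in the lists, so no ratio can be given.

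The third comparison asked whether 5hmC differed in level where both libraries had a peak. In 26954 pairs that overlapped one to one, tag density scaled to kept tags was higher in the AA-labelled library in 75.2%, but the median difference turned round when tags were scaled to the tags inside peaks (log2 ratio -0.31) or not scaled (-0.41). With the first scaling the median density was 2.32 tags per kb and 1000000 kept tags in the AA-labelled library and 2.00 in the other. The median log2 ratio was 0.22 (0.21 to 0.22 over pairs), or 1.16-fold, with quartiles of 0.00 and 0.45. In density per kb, 397 pairs were over 2-fold higher and 6 over 2-fold lower in the AA-labelled library, and in tags per peak, not divided by length, 5523 (20.5%) and 110 were. The peaks of these pairs were called longer in the AA-labelled list, at a median of 1099.5 bp against 884 bp, and a longer peak takes in more tags. By fold enrichment the counts were 603 and 52. The density ratio grew with strength, from 0.15 in the weakest 20% of the pairs by p to 0.36 in the strongest 20%. This rise rested in part on the division by peak length: tags per peak gave 0.51, 0.49, 0.48, 0.50 and 0.59 from the weakest to the strongest class. A scaling shifts every pair by the same amount, so it leaves the order of the classes as it is and changes the sign and the counts of 2-fold differences.

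**Figure D2:**
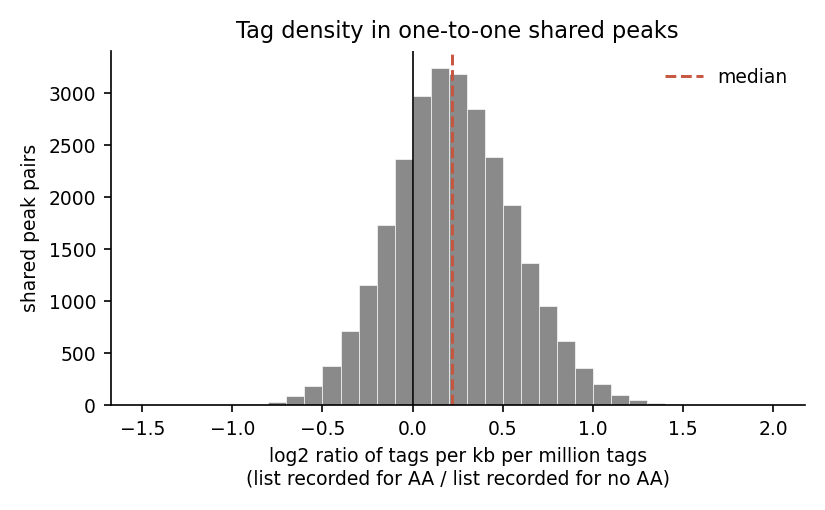
Number of shared peak pairs (y axis) by the log2 ratio of tags per kb and 1000000 kept tags, AA-labelled over no-AA-labelled (x axis, bins of 0.1), for 26954 one-to-one pairs of 1 library each. The dashed line marks the median of 0.22 and the solid line marks 0; 75.2% of the pairs lie above 0, and with scaling to the tags in peaks the median moves to -0.31, below 0.

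Single pairs were compared with this median of 0.22. The largest density ratio among pairs with at least 30 tags in 1 library was on chromosome 19 (11297382 to 11298539), with 79 AA-labelled and 42 no-AA-labelled tags and a log2 ratio of 1.71 (1.15 to 2.28). It was followed by chromosome 15 (103260434 to 103261185) at 1.65 (0.87 to 2.49), chromosome 18 (7548784 to 7549356) at 1.63, chromosome 10 (33957553 to 33958386) at 1.58 and chromosome X (64632269 to 64633846) at 1.57. The lowest ratio was on chromosome 5 (14933651 to 14934436), with 15 against 37 tags and a log2 ratio of -1.28 (-2.25 to -0.38). Then came chromosome 12 (21586095 to 21587046) at -1.19, chromosome 5 (37051816 to 37052382) at -1.07, chromosome 2 (6399159 to 6400541) at -1.04 and chromosome 3 (112140584 to 112141301) at -1.03. Part of this came from unequal peak lengths. The chromosome 2 pair had 25 AA-labelled tags in 1383 bp and 34 no-AA-labelled tags in 590 bp, and its ratio in tags per peak was 0.18 (-0.62 to 0.97), an interval that includes the median of 0.52 for that measure. The intervals of the other 4 lowest and the 5 highest pairs excluded that median, on the same side as in density. These are the ends of a distribution of 26954 pairs, and their intervals are not adjusted for that choice.

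The fourth comparison asked how the peaks were spread over the chromosomes. Both lists had their highest peak density on chromosome 8 and then on chromosome 1, and a low density on chromosome X. Chromosome 8 had 28.8 AA-labelled and 34.6 no-AA-labelled peaks per Mb, and chromosome 1 had 26.9 and 32.4. The other 17 autosomes ranged from 19.3 to 25.5 peaks per Mb in the AA-labelled list and from 20.7 to 26.5 in the other. Chromosome X had 8.71 and 10.3 peaks per Mb, which was 0.392 and 0.419 times the median autosome. Peak densities were not corrected for the number of copies of a chromosome in the cells, on which the tags per site depend. The median fold enrichment of chromosome X was above the median autosome's, at 9.90 against 7.88 in the AA-labelled list and 8.59 against 6.99 in the other. Its peaks held fewer tags, with a median of 23 and 25 against 27 and 28 in the whole lists. A background worked out from tags, lengths and folds was 0.574 and 0.572 times the genome-wide level there, lower than on any autosome. The higher fold thus went with a lower background and does not show more 5hmC per site. Peaks on chromosome X were also more often shared, at 65.5% and 56.5%, where no autosome passed 54.5% and 45.9%.

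**Figure D3:**
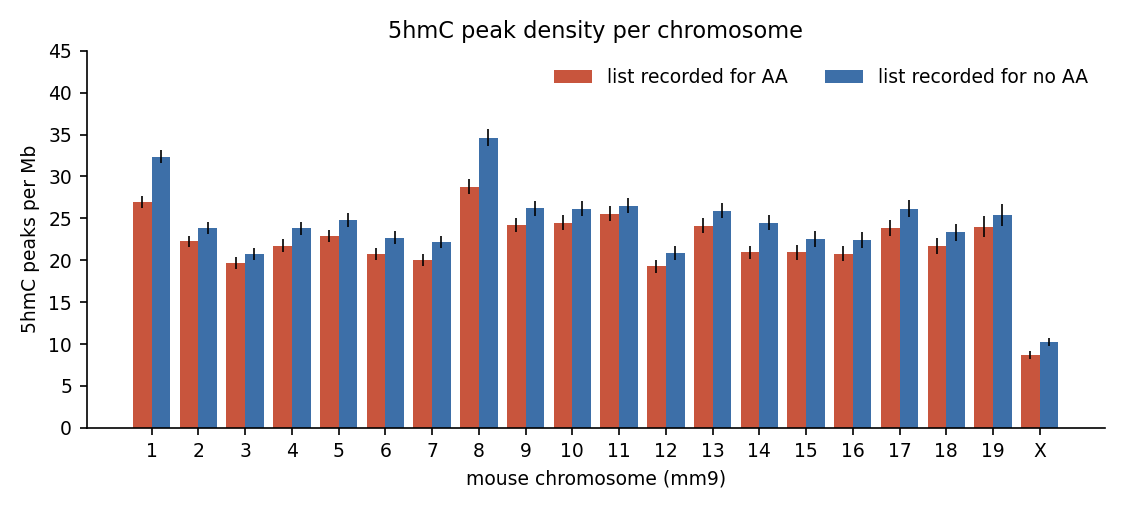
5hmC peaks per Mb (y axis) on mouse autosomes and chromosome X (x axis) in the AA-labelled list (red) and the no-AA-labelled list (blue), 1 library each, with Poisson 95% intervals for counting error. Chromosomes 1 and 8 stand above the other autosomes in both lists, at 26.9 and 28.8 peaks per Mb in the AA-labelled list, and chromosome X lies lowest at 8.71.

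The AA-labelled list had fewer peaks on each of the 19 autosomes, but not to the same extent. The ratio of AA-labelled to no-AA-labelled peaks was 0.832 on chromosome 1 (0.803 to 0.863), 0.831 on chromosome 8 (0.795 to 0.868), 0.855 on chromosome 14 (0.811 to 0.901) and 0.849 on chromosome X (0.791 to 0.911). The median of the 17 autosomes other than 1 and 8 was 0.926. The highest ratio was on chromosome 11, at 0.964 (0.917 to 1.01), and the intervals of chromosomes 11 and 19 (0.880 to 1.02) reached past 1. On chromosome 1 all 10 windows of 20 Mb lay below the ratio of all peaks, between 0.772 and 0.882. On chromosome 8 it was 6 of 7 windows, and all 7 ranged from 0.756 to 0.929. On chromosome X the difference was largest in 1 stretch: between 140 and 160 Mb, chosen after its values were seen, the lists held 306 and 445 peaks (ratio 0.688, 0.593 to 0.797), and the rest of the chromosome had a ratio of 0.905 (0.835 to 0.981). The 2 mitochondrial peaks, with 138 and 309 tags, were in the no-AA-labelled list, and chromosome Y had 11 and 14 peaks.

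**Figure D4:**
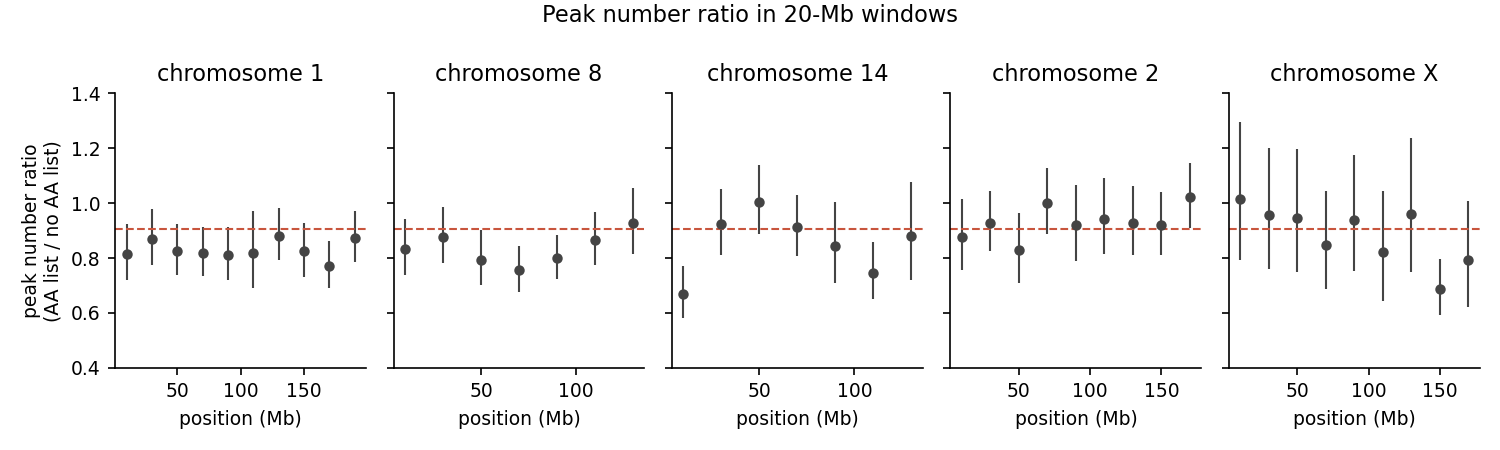
Ratio of AA-labelled to no-AA-labelled peak number (y axis) in 20-Mb windows along chromosomes 1, 8, 14, 2 and X (x axis, position in Mb; windows with at least 100 no-AA-labelled peaks), with exact 95% intervals for counting error. The dashed line is the ratio of all peaks, 0.906; the windows of chromosome 1 all lie below it, while the lowest windows of chromosomes 14 and X are at 0.670 and 0.688.

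At the scale of 1 Mb the lists had nearly the same landscape. Across 2580 windows of the autosomes and chromosome X, the peak numbers had a Pearson correlation of 0.907 and a Spearman correlation of 0.923. These run across windows of single libraries, which are not independent replicates. The median window held 21 AA-labelled and 24 no-AA-labelled peaks, and the fullest 71 and 92. The windows with the largest excess in the AA-labelled list, after scaling to the list totals, began at 107 Mb on chromosome 12 (50 against 31 peaks, ratio 1.61, 1.01 to 2.61), 31 Mb on chromosome 9 (46 against 28) and 71 Mb on chromosome 2 (51 against 35). The windows with the largest deficit were all near the start of chromosome 14, at 4 Mb (28 against 59 peaks, ratio 0.475, 0.291 to 0.756), 7 Mb (30 against 59) and 5 Mb (24 against 49). In the first of these, 26 of the 28 AA-labelled peaks were shared, and 28 of the 59 no-AA-labelled peaks. The windows named for an excess or a deficit are the ends of a distribution of 2580 windows. Their intervals are not adjusted for that choice, and counting error alone can give such ends. The value to set them beside is the ratio of all peaks, 0.906, not 1.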

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

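The exchange of the lists, the local shifts, the scaling to tags before duplicate removal, the strong pairs, the fold enrichment times fragment length and the removal of tag-dense peaks were chosen after seeing the data. The log2 ratio of peak numbers, AA-labelled over no-AA-labelled, was -0.14 and turned to 0.17 with a p of at most 1e-10 and to 0.91 with a fold enrichment of at least 10, since the AA-labelled list holds more strong peaks. That of the covered length was 0.27 and moved to 0.47 and 1.25 at these cutoffs. With the lists exchanged as their headers name them, peak number became 0.14, covered length -0.27 and tag density in shared peaks -0.22. The shared percentages of 47.5 and 43.6 became 46.8 and 42.9 when 50% of the shorter peak had to overlap, 41.5 and 37.6 with 50% reciprocal overlap, 49.3 and 45.7 within 500 bp, 43.4 and 48.9 with a p of at most 1e-10 in both lists, 22.1 and 41.8 with a fold enrichment of at least 10 in both, and 45.2 and 45.7 with lists of equal length. Local shifts of 50 to 500 kb put the chance level at 6.77% and 6.18%. The median log2 ratio of 0.22 in shared peaks became 0.52 for tags per peak, -0.41 without scaling, -0.31 with scaling to tags in peaks, 0.21 for fold enrichment, 0.37 with scaling to tags before duplicate removal, 0.36 for pairs with a p of at most 1e-10 in both lists and 0.68 for fold enrichment times fragment length. The last is not a separate tag measure: it is the 0.21 of the fold enrichment moved by the ratio of the fragment lengths, alike for every pair. Each scaling is 1 factor for every pair and so moves all pairs alike, and of the 3 other scalings the absence of one and that to tags in peaks turned the sign. For the other values that moved, the cause was not tested. Chromosome 8 against the rest, at -0.13, became -0.25 with a p of at most 1e-10. The correlation of 1-Mb windows, 0.907, became 0.780 with 250-kb and 0.956 with 5-Mb windows. The other 11 alternatives, among them chromosomes 1 and X under every setting tried, stayed within the interval set around the main value. For covered lengths that interval was carried over from peak numbers, and for tag density it covers the spread over pairs only. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The FDR and promoter alternatives were not run, since the lists hold no FDR column and no annotation of the build was used. Depth limits the weaker peaks most: the median peak held 27 and 28 tags, and a peak absent from a list may hold tags just short of the cutoff.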

Other observations

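All tests in this part except that on peaks with a p of at most 1e-10 on chromosomes 1 and 8 were chosen after the result was seen. The densest 1-Mb windows, chosen after their values were seen, were 2 neighbours on chromosome 4 at 145 Mb (71 AA-labelled and 92 no-AA-labelled peaks) and 146 Mb (68 and 90), against a median of 21 and 24. Of the AA-labelled peaks in these windows, 61 and 53 were shared. Windows at 67 Mb (57 and 69 peaks) and 48 Mb (50 and 72) on chromosome 8 and at 37 Mb on chromosome 18 (57 and 63) came next. On chromosome X the stretch from 140 to 160 Mb held 15.3 and 22.3 peaks per Mb, and the rest of the chromosome 7.81 and 8.63. On chromosome 14 the stretch from 3 to 9 Mb, its bounds chosen after the values were seen, had 167 AA-labelled and 318 no-AA-labelled peaks (ratio 0.525, 0.433 to 0.635), with 24 to 31 and 49 to 59 peaks in every 1-Mb window. The rest of that chromosome had a ratio of 0.893 (0.845 to 0.943), with a further low stretch, also chosen after its values were seen, from 100 to 120 Mb (367 against 491 peaks, ratio 0.747, 0.651 to 0.857).

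A few peaks, chosen after their values were seen, held far more tags than the rest. On chromosome 2, the peak from 98506208 to 98508024 held 1496 AA-labelled tags, or 0.823 tags per bp, and its no-AA-labelled counterpart 1527 tags, against medians of 0.0264 and 0.0349 tags per bp. The largest counts were not all shared: the no-AA-labelled list had unshared peaks on chromosome 8 at 19970009 to 19978287 (1849 tags, its highest count, 3.51-fold), 19978313 to 19984129 (1447, 5.29-fold) and 20020366 to 20026678 (735, 4.70-fold) and on chromosome 11 at 3076198 to 3080354 (815, 3.21-fold), and the AA-labelled list had 1 on chromosome 11 at 3088485 to 3095979 (1472, 7.19-fold). These folds lay below the medians of their lists, 7.05 and 7.86. The peaks at 19970009 and 19978313 adjoin each other, and the AA-labelled one adjoins a shared peak that ends at 3088475. They are thus parts of tag-rich stretches. With no input library, they are not shown to be sites of 5hmC in 1 list only. Peaks above 0.25 tags per bp numbered 8 and 12, with 5402 and 5897 tags in all. Neighbouring peaks within 5 kb of each other were rarer than in uniform placement, at 8.41% of gaps against 13.4% in the AA-labelled list and 10.4% against 14.1% in the other. The peaks of a list do not overlap, and the caller took its regional background over 10000 bp of the same library. Fewer short gaps can thus come from the calling itself, and no conclusion on the placement of 5hmC is drawn.

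The AA-labelled list had relatively few peaks on chromosomes 1 and 8, and a few regions are argued against as the cause: 31 of the 34 windows of 10 Mb on these chromosomes, 91.2%, lay below the median window of the other autosomes. Weak peaks near the cutoff of the deeper library are argued against too, since among peaks with a p of at most 1e-10 the log2 ratio against the rest was -0.17 (SE 0.06) and -0.25 (SE 0.07), a mean of -0.21. Each SE covers counting error only and takes the counts of both lists as independent, though most of these peaks were shared. A p of 1e-10 depends on depth as well, so other effects of depth are not excluded. Extra copies of chromosome 8, a known recurrent change in cultured mouse ES cells, in the cells of the no-AA-labelled library are a candidate explanation. For shared pairs with a p of at most 1e-10 in both lists, the log2 tag ratio was taken against the other 17 autosomes. It differed by -0.088 from their median and lay below each of them, as did the tags per kb. No interval was worked out for this difference, and it says nothing of copies that both libraries share. A chromosome-wide difference in 5hmC would lower these tags as well, and chromosome 8 was singled out for its low peak ratio in these same lists. A background worked out from tags, lengths and folds had its highest no-AA-labelled to AA-labelled ratio of the autosomes there, 0.984. This measure divides the mean tag depth of a peak by its fold, so it may vary with peak shape too. On chromosome 8 it was 0.893 and 0.879 times the genome-wide level. Its ratio was higher still on chromosome X (0.996), where the tags of such pairs were not low (0.66, and 0.41 per kb). No conclusion on copies is therefore drawn from it. For chromosome 1 the tags (a difference of -0.047) lay below all of the other 17 autosomes, but the tags per kb (0.34) lay within their range (0.32 to 0.43). The ratio of the background measure (0.976) lay above all of these autosomes (highest 0.972), with the same limit. Copy number and a chromosome-wide difference in 5hmC thus cannot be told apart on either chromosome. An effect of AA stays open for both chromosomes with 1 library per group.

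Each list held more peaks without a counterpart in the other than with one. Peaks near the cutoff are a candidate explanation for many of these, since the shared part rose to 88.8% or more in the 10% of each list with the smallest p and was 27.7% or less in the 10% nearest the cutoff. By fold enrichment, which does not measure the distance from the p cutoff, the shares were closer, at 72.6% and 60.9% in the highest 10% and 39.2% and 41.5% in the lowest, so that peaks of high fold were often unshared too. Gain and loss of 5hmC with AA may account for some of the strong unshared peaks, of which the AA-labelled list had 3163 of 13247 and the other 2435 of 11777, a ratio of counts of 1.30 that comes in part from the larger number of such peaks in the AA-labelled list (76.1% and 79.3% of them were shared). Without a second library of either group, the number that 2 libraries of the same cells would leave unshared is unknown, so this cannot be told apart from variation between libraries.

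The headers of 2 of the 2 lists name the other sample. An exchange of the 2 lists before deposit may have occurred, or the names of the runs may have been exchanged before peak calling and set right later. As recorded, the AA-labelled library had fewer peaks at the authors' cutoff and a larger share of its tags in them. With the 2 lists exchanged, the library with AA would have more peaks at that cutoff (log2 ratio 0.14). Its tag density in shared ones, scaled to kept tags, would be lower (-0.22). Stricter cutoffs turn the first of these round, and scaling to the tags in peaks turns the second. The lists hold nothing known beforehand of either library, such as its tag total, so the record and the headers cannot be told apart.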
